A study of Mus with 15 samples.

How the data were processed

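The deposited table held whole-number read counts per gene for 15 libraries, and the authors made the libraries from poly-A RNA with a kit that does not mark the strand, per the labels. The aligner, the counting program, the strand setting and the genome build are not given in the sources used here. The 5 diabetic columns carry the numbers 5 to 9 in the table and were taken as replicates 1 to 5 in that order. Time after wounding, strain and the way diabetes was induced are not given in the sources used here. The table had 55657 gene models, of which 54532 had a symbol and 1125 were models without one. Of the symbols, 37795 matched a RefSeq annotation of the mouse genome, and 94.3% of those had gene ends within 5000 bp of it, but coordinates are printed as the table gives them. Models with 105 duplicated symbols were kept apart by identifier.

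Counts were tested with the edgeR 4.0.16 quasi-likelihood F-test (robust, TMM normalization, filterByExpr) in R 4.3.3, in 1 fit over the 3 groups with 12 residual degrees of freedom. Calls used a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 32 lists and 3 comparisons. The same test was run with a correlation estimated for each list, and fry served as a self-contained test. Member calls were counted over all genes tested and adjusted over the list alone. The lists, tests, comparisons, rule for named genes and other settings were chosen before the data were examined. Of these lists, 12 per comparison were described gene by gene, a choice made after the list results were seen.

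Named genes were chosen by rule. The first part took the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap in CPM and whose higher group had a mean of at least 10 CPM, leaving out symbols beginning with Gm, ending in Rik or made of bare identifiers, which were taken to include clone names. The second part took the 3 members with the smallest p of each list described. The third part was 18 fixed genes. Of the genes this rule names, 2 are not reported here, and no others were put in their place. Genes outside the rule are named where a count is 5 or fewer, or as said in the text, and were chosen after their values were seen.

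Means are given with the SD over 5 libraries and fold changes with their SE. Where a group was at 0 counts, a floor of 3 counts over the group gave a bound, and with 1 to 3 counts a ratio with a 95% counting interval is given. Floors and intervals cover counting error only. The mean depth was 16.9, 17.5 and 16.2 M counts in normal skin, healthy wound and diabetic wound.

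The procedure was tested on simulated data with 16816 genes tested. At a log2 fold change of 1 it called 16 of 97 changed genes in each diabetic comparison, and at 2 it called 53 of 98 against normal skin and 57 of 98 against healthy wound. It called 2 unchanged genes in each of these, and 0 in the simulated healthy wound comparison, where no gene was changed. A list moved by 1 had camera adjusted p-values of 1.97e-17 and 7.76e-13, and 0 of the unmoved lists were called. Genes were drawn independently, so this check could not show false list calls that arise when genes vary together.

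Alternatives were RLE, upper-quartile and library-size scaling, no low-count filter, a stricter filter (at least 1 CPM in at least 5 libraries and a mean of at least 5 CPM), DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit of 2 groups alone, the replicate number as a block, a minimum log2 fold change of 1 and leaving out each library in turn. Leaving out diabetic wound replicates 4 and 5 together was added after the data were seen. Exact permutation tests of 5 against 5 libraries have a smallest p of 0.00794.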

Results

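Poly-A RNA was sequenced from mouse skin in 3 groups of 5 libraries: uninjured skin of healthy mice (normal skin), wound tissue of healthy mice (healthy wound) and wound tissue of mice with type I diabetes (diabetic wound). The series title concerns mesenchymal stem cells without nuclei and wound repair, and the 3 groups address how wounding changed skin RNA and how a wound of a diabetic mouse differed from that of a healthy mouse. Uninjured diabetic skin was not analysed here. The mean depth was 16.9 ± 0.862 M counts in normal skin, 17.5 ± 0.114 M counts in healthy wound and 16.2 ± 0.362 M counts in diabetic wound (SD, n = 5 per group). Of 55657 gene models in the table, 17122 had enough counts to be tested. The labels give mice as the source without saying that each library came from a separate animal, so p-values measure the spread between these samples. Between libraries of a group the lowest chi-square per degree of freedom was 40.39, 36.76 and 70.72 in normal skin, healthy wound and diabetic wound. These values lie far above counting noise and argue against repeat sequencing of the same library. The spread may still be technical, from sample preparation, and shared animals stay open.

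Diabetic wounds lay apart from the other libraries on the first principal component of log2 CPM (counts scaled to library size), which held 31.2% of the variance; the second held 15.8%. Normal skin and healthy wound overlapped on the first component. The median Pearson correlation across genes between libraries was 0.91 within normal skin, 0.939 within healthy wound and 0.908 within diabetic wound. It was 0.898 between diabetic and healthy wounds, 0.883 between diabetic wounds and normal skin, and 0.916 between healthy wounds and normal skin. Genes are not independent replicates, so these values carry no test.

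**Figure D1:**
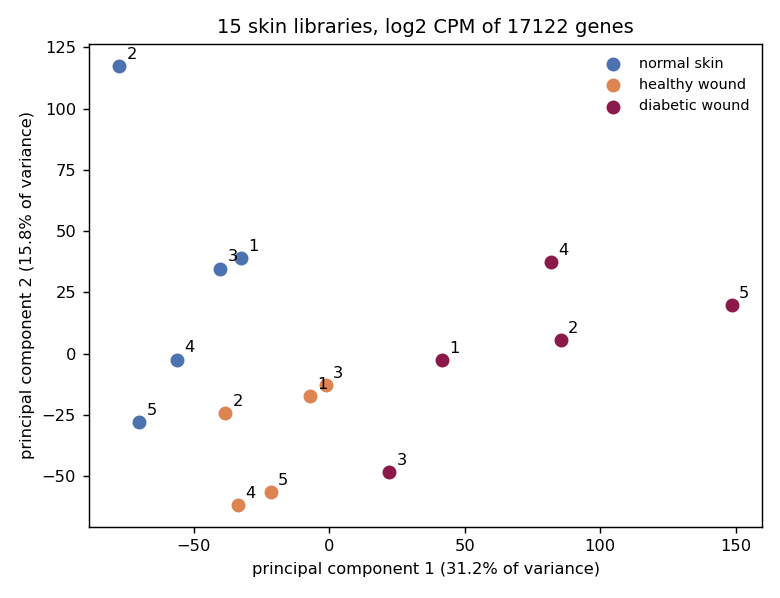
Scores of the 15 libraries on the first 2 principal components of log2 CPM over 17122 genes; each point is a library and the number beside it is its replicate. The diabetic wounds spread from 22.2 (replicate 3) to 149 (replicate 5) on the first component, and all lie above the other libraries.

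The samples also differed in tissue content. The mean log2 CPM of 19 skeletal muscle genes was 9.47 ± 1.22 in normal skin, 7.51 ± 1.22 in healthy wound and 8.31 ± 1.02 in diabetic wound (SD, n = 5 per group), and that of 18 adipocyte genes was 7.03 ± 0.30, 5.66 ± 0.64 and 4.63 ± 1.10 in the same order. Cornified epidermal genes had means of 8.19 ± 0.68, 7.25 ± 0.90 and 6.28 ± 1.86, and in the diabetic wounds ranged from 3.83 to 8.04 between libraries. Hair follicle and hair keratin genes had means of 2.45 ± 3.21, 2.38 ± 3.68 and −1.71 ± 0.44. Transcripts of the fibrillar collagen genes Col1a1, Col1a2 and Col3a1 took 3.86 ± 0.764% of counts in normal skin, 5.22 ± 2.63% in healthy wound and 0.784 ± 0.610% in diabetic wound.

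Camera called lists of neutrophil, cytokine and protease genes higher in healthy wound than in uninjured skin, and lists of sebaceous and adipocyte genes lower (each adjusted p = 0.36 with an estimated correlation). The largest rise among the named genes was that of Cxcl5, a chemokine that attracts neutrophils (ENSMUSG00000029371; chromosome 5, 90759360 to 90761624, plus strand), from 0.151 ± 0.192 CPM in normal skin to 101 ± 118 CPM in healthy wound (SD, n = 5 per group; log2 fold change 9.39, SE 1.15, edgeR adjusted p = 0.00779). Arg1, arginase 1, which converts arginine to ornithine (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484, minus strand), rose from 9.05 ± 2.37 to 213 ± 183 CPM (log2 fold change 4.56, SE 0.60, edgeR adjusted p = 0.00868). The acute-phase gene Saa3 rose by 4.15 (SE 0.73) on the log2 scale, the prokineticin receptor gene Prokr2 by 5.08 (SE 1.12) and the epidermal envelope gene Sprr2i by 4.72 (SE 0.90), with edgeR adjusted p-values of 0.0206, 0.043 and 0.028. Krt77, a type II keratin of skin (chromosome 15, 101858731 to 101869705, minus strand), fell from 3193 ± 893 to 186 ± 163 CPM (log2 fold change −4.10, SE 0.88, edgeR adjusted p = 0.0397). Scd3, a stearoyl-CoA desaturase of sebaceous glands, changed by −2.96 (SE 0.48) on the log2 scale and Adh6a, of the alcohol dehydrogenase family, by −3.90 (SE 0.81). Myoc (myocilin) changed by −3.40 (SE 0.71), the complement gene C7 by −2.93 (SE 0.50) and the hemicentin gene Hmcn2 by −2.64 (SE 0.57). These 5 genes had edgeR adjusted p-values between 0.0154 and 0.0397. Of the genes in this paragraph only Cxcl5 and Arg1 were called without healthy wound replicate 5. Without 1 library the log2 fold change of Cxcl5 was 8.38 (healthy wound replicate 3) or 10.34 (normal skin replicate 2), and that of Arg1 was 3.91 (healthy wound replicate 5). Prokr2 was at 7.88 and Saa3 at 5.01 without normal skin replicates 1 and 3, and Sprr2i at 4.01 and Krt77 at −4.76 without healthy wound replicates 1 and 4.

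Of the 17 neutrophil markers, 7 rose over all genes tested and 13 rose adjusted over the list alone, and all 17 had positive fold changes (median log2 fold change 3.12, camera adjusted p = 1.15e-12). The list of neutrophil markers had a camera adjusted p = 0.36 with an estimated correlation. They included S100a9 and S100a8, the subunits of calprotectin, at 999 ± 606 and 801 ± 492 CPM in healthy wound against 53.3 ± 45.6 and 63.2 ± 61.1 CPM in normal skin (SD, n = 5 per group; log2 fold changes 4.23 and 3.66), and the collagenase gene Mmp8 (log2 fold change 3.46, edgeR adjusted p = 0.0154). Of 22 inflammatory cytokine and chemokine genes, Cxcl5 alone rose over all genes tested and 13 rose adjusted over the list alone (median 2.58, camera adjusted p = 7.11e-11). The list of inflammatory cytokine and chemokine genes had a camera adjusted p = 0.36 with an estimated correlation. The 17 monocyte and macrophage markers had positive fold changes in every case, but none passed over all genes tested and 3 passed adjusted over the list alone (median 0.80, camera adjusted p = 3.24e-05; adjusted p = 0.494 with an estimated correlation); at unadjusted p under 0.05, 2793 genes of the whole table passed in edgeR. Of 22 interferon-stimulated genes, only Ifi44 rose by either adjustment (log2 fold change 2.14, SE 0.48, edgeR adjusted p = 0.0471), and the list was higher by camera (median 1.23, adjusted p = 3.57e-09). The list of interferon-stimulated genes had a camera adjusted p = 0.36 with an estimated correlation. None of S100a9, S100a8, Mmp8 and Ifi44 was called without healthy wound replicate 5, and S100a9 and S100a8 were at 4.88 and 4.38 without normal skin replicate 1.

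Of 20 proteases of matrix turnover and their inhibitors, 5 rose over all genes tested, and adjusted over the list alone 10 rose and 1 fell (median log2 fold change 1.56, camera adjusted p = 6.94e-08). The list of proteases of matrix turnover and their inhibitors had a camera adjusted p = 0.36 with an estimated correlation. Among them Adam8, a membrane metalloprotease of leukocytes, rose by 2.24 (SE 0.34) and Timp1, an inhibitor of metalloproteases, by 2.86 (SE 0.51), with edgeR adjusted p-values of 0.0154 and 0.0211. Of 21 wound-edge keratinocyte genes, Itga5 (log2 fold change 1.89) and Serpinb3a (4.10) rose, and 8 rose adjusted over the list alone (median 1.71, camera adjusted p = 1.03e-08). The list of wound-edge keratinocyte genes had a camera adjusted p = 0.36 with an estimated correlation. Of 20 endothelial and angiogenesis genes, Pgf, placental growth factor, rose by 2.39 and 11 rose adjusted over the list alone (median 1.04, camera adjusted p = 5.05e-08). The list of endothelial and angiogenesis genes had a camera adjusted p = 0.36 with an estimated correlation. Of 24 collagen and extracellular matrix genes, Thbs1 (thrombospondin 1) rose by 2.88 and 7 rose adjusted over the list alone (median 0.79, camera adjusted p = 0.00045). The list of collagen and extracellular matrix genes had a camera adjusted p = 0.649 with an estimated correlation. Col1a1 and Col3a1 had log2 fold changes of 0.27 (SE 0.69) and 0.73 (SE 0.69), which were within the spread between libraries (edgeR adjusted p = 0.918 and 0.692). None of Adam8, Timp1, Itga5, Serpinb3a, Pgf and Thbs1 was called without healthy wound replicate 5, and Serpinb3a was at 3.37 without healthy wound replicate 1.

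Some lists of other skin tissues were called lower in healthy wound by camera, while basal keratinocyte genes were not called (median −0.08, camera adjusted p = 0.924). All 19 skeletal muscle genes had negative fold changes; none passed over all genes tested, where 2793 genes had an unadjusted p under 0.05 in edgeR, and 16 fell adjusted over the list alone (median log2 fold change −2.01, camera adjusted p = 3.67e-11). The list of skeletal muscle genes had a camera adjusted p = 0.36 with an estimated correlation. Of 18 adipocyte genes, Acvr1c fell over all genes tested and 4 fell adjusted over the list alone (median −1.33, camera adjusted p = 5.63e-09). The list of adipocyte genes had a camera adjusted p = 0.36 with an estimated correlation. Of 16 sebaceous gland genes, Scd3 fell and 2 fell adjusted over the list alone (median −0.58, camera adjusted p = 0.000349); reads of Scd3 can be shared with its close relative Scd1. The list of sebaceous gland genes had a camera adjusted p = 0.36 with an estimated correlation. Of 22 cornified epidermal genes, Krt77 fell by both adjustments (median −0.65, camera adjusted p = 0.00202). The list of cornified epidermal genes had a camera adjusted p = 0.701 with an estimated correlation. Of 26 nuclear genes of oxidative phosphorylation, Ndufv1 fell and 8 fell adjusted over the list alone (median −0.33, camera adjusted p = 3.59e-07). The list of nuclear genes of oxidative phosphorylation had a camera adjusted p = 0.36 with an estimated correlation. Camera also called the lists of homing ligands (median 0.83, adjusted p = 0.00232; adjusted p = 0.36 with an estimated correlation), oxidative stress genes (0.31, adjusted p = 0.0048; 0.36 with an estimated correlation) and hypoxia genes (0.39, adjusted p = 0.0066; adjusted p = 0.583 with an estimated correlation) higher. Hair genes had a positive median of 0.78 while camera ranked the list downwards without a call (camera adjusted p = 0.608). None of Acvr1c, Scd3 and Krt77 was called without healthy wound replicate 5.

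By edgeR, 133 genes were higher and 60 lower in healthy wound than in normal skin at a Benjamini-Hochberg adjusted p under 0.05, and 2793 had an unadjusted p under 0.05. Of these called genes, 97 higher and 40 lower ones had a mean of at least 10 CPM and groups that did not overlap. Chance gives 0.794% of genes not chosen by a test, which is no baseline for genes already called on the same libraries. The number of genes called, 193 in all, fell when any 1 library of these groups was left out except healthy wound replicate 2, where 269 were called. It was 59, 100, 92, 10 and 71 without normal skin replicates 1, 2, 3, 4 and 5 in turn. It was 34, 26, 65 and 3 without healthy wound replicates 1, 3, 4 and 5. Without diabetic wound replicates 4 and 5 together, a choice made after the data were seen, 605 were called. A fit of these 2 groups alone called 537, so the count of 193 depends on the diabetic libraries in the fit. Of the 22 named genes that passed, Arg1 and Cxcl5 did so in all 10 fits that left out 1 library. The camera calls of 3 further lists were lost without some single libraries. Melanocyte genes (median −1.60, camera adjusted p = 0.0329, or adjusted p = 0.677 with an estimated correlation) were not called without normal skin replicate 5 or healthy wound replicates 1, 2 and 3 (camera adjusted p = 0.341, 0.102, 0.0744 and 0.0723). Schwann cell genes (median −0.61, camera adjusted p = 0.035, or adjusted p = 0.68 with an estimated correlation) were not called without normal skin replicates 1, 3 and 4 or healthy wound replicates 2 and 3 (camera adjusted p = 0.241, 0.195, 0.058, 0.145 and 0.0609) or without diabetic wound replicates 4 and 5 together (0.0517). Cell cycle genes (median 0.27, camera adjusted p = 0.0224, or adjusted p = 0.725 with an estimated correlation) were not called without normal skin replicates 1, 2 and 3 (0.261, 0.0545 and 0.197).

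Camera called lists of neutrophil, chemokine and oxidative stress genes higher in diabetic wound than in uninjured healthy skin, and lists of adipocyte, sebaceous, melanocyte and T cell genes lower. With an estimated correlation the camera adjusted p was 0.582 for the melanocyte list and 0.36 for the others. Cxcl5 rose from 0.151 ± 0.192 to 373 ± 303 CPM (SD, n = 5 per group; log2 fold change 11.27, SE 1.21, edgeR adjusted p = 0.000346), and the neutrophil chemokine genes Cxcl1 and Cxcl3 rose by 8.24 (SE 1.51) and 7.21 (SE 1.68) on the log2 scale (edgeR adjusted p = 0.00392 and 0.0113). Diabetic wound replicate 5 held 691 CPM of Cxcl1 and the others between 8.73 and 103, and without it the log2 fold change was 6.05. Normal skin replicate 1 held 156 of the 158 counts of Cxcl3 in its group. Without that library Cxcl3 was at 12.88 and Cxcl1 at 9.16, and Cxcl3 was at 6.18 without diabetic wound replicate 5. Ngp, a neutrophil granule gene (ENSMUSG00000032484; chromosome 9, 110419747 to 110423012, plus strand), rose by 8.91 (SE 1.72, edgeR adjusted p = 0.0049); diabetic wound replicate 5 held 311 CPM of Ngp and the other diabetic libraries between 1.55 and 7.44. The Ngp log2 fold change was 4.96 without it and 9.98 without normal skin replicate 3. Cbln1, a cerebellin gene, rose by 8.77 (SE 1.61, edgeR adjusted p = 0.00392), with 279 CPM in diabetic wound replicate 5 and 0.515 to 25.1 CPM in the others. Without that replicate the Cbln1 log2 fold change was 6.16, and 9.65 without normal skin replicate 4. Il19, a cytokine gene of the interleukin 10 family, had 2 counts in all of normal skin and a ratio of diabetic wound to normal skin of 636 (95% counting interval 176 to 5252; edgeR adjusted p = 0.00327). The Il19 ratio rested on diabetic wound replicate 5, at 66.4 CPM against 0.912 to 4.42 CPM in the others. The log2 fold change of 8.92 became 6.12 without it. Lep, the leptin gene of adipocytes (ENSMUSG00000059201; chromosome 6, 29060220 to 29073877, plus strand), fell from 22.8 ± 4.05 to 0.237 ± 0.53 CPM (log2 fold change −6.54, SE 1.04, edgeR adjusted p = 0.00227), and its counts in diabetic wound came from replicate 3 alone. Hhip, a hedgehog-binding protein gene, changed by −5.80 (SE 1.03), Golga7b by −6.15 (SE 1.14) and the muscle gene Ky by −4.96 (SE 0.82), with edgeR adjusted p-values between 0.0025 and 0.00414. Without 1 library Hhip was at −4.76 and Golga7b at −5.08 (normal skin replicate 5), and Ky at −4.33 and Cxcl5 at 12.23 (normal skin replicate 2). Lep was fitted at −11.59 without diabetic wound replicate 3. No counts of Lep were then left in that group, so the counts do not set the size of this value.

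Of the 17 neutrophil markers, 14 rose over all genes tested and 15 rose adjusted over the list alone (median log2 fold change 3.83, camera adjusted p = 2.59e-10). The list of neutrophil markers had a camera adjusted p = 0.36 with an estimated correlation. Mmp8 rose from 1.39 ± 1.11 to 67.9 ± 43.5 CPM and the myeloid lectin gene Clec4d from 9.85 ± 9.86 to 232 ± 130 CPM (SD, n = 5 per group; edgeR adjusted p = 0.000346 and 0.00297). Of 22 inflammatory cytokine and chemokine genes, 11 rose and 15 rose adjusted over the list alone, among them Ccl2 (log2 fold change 3.74, SE 0.82) and Il6 (5.26, SE 1.26) (median 2.92, camera adjusted p = 2.17e-06). The list of inflammatory cytokine and chemokine genes had a camera adjusted p = 0.36 with an estimated correlation. Il1b and Tnf had log2 fold changes of 3.57 (SE 1.22) and 2.82 (SE 1.04) that did not pass (edgeR adjusted p = 0.0519 and 0.0682). Of 17 monocyte and macrophage markers, Itgam, Cd14, Fcgr1 and Ly6c2 rose by either adjustment (median 0.66, camera adjusted p = 0.0302). Camera did not call this list without normal skin replicate 5 or diabetic wound replicates 3 and 4 (adjusted p = 0.129, 0.218 and 0.112). The list of monocyte and macrophage markers had a camera adjusted p = 0.701 with an estimated correlation. Of 22 oxidative stress response genes, 13 rose and 16 rose adjusted over the list alone (median 0.95, camera adjusted p = 6.05e-06), among them the heme oxygenase gene Hmox1, from 117 ± 66.2 to 653 ± 333 CPM, and Slc7a11, the cystine transporter gene (log2 fold change 3.15, SE 0.57). The list of oxidative stress response genes had a camera adjusted p = 0.36 with an estimated correlation. Of 23 hypoxia and glycolysis genes, 8 rose by either adjustment, including Hif1a (1.26, SE 0.26), the glucose transporter gene Slc2a1 (1.46, SE 0.29) and the pyruvate kinase gene Pkm (1.09, SE 0.18) (median 0.46, camera adjusted p = 0.00565). The list of hypoxia and glycolysis genes had a camera adjusted p = 0.582 with an estimated correlation. Diabetic wound replicate 5 weighed on Ccl2 and Il6, at 2.67 and 4.42 without it. Il6 was at 6.30 without normal skin replicate 2, and Clec4d at 5.37 instead of 4.55 without normal skin replicate 1.

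Of 20 matrix proteases and inhibitors, 8 rose, and adjusted over the list alone 9 rose and 1 fell (median log2 fold change 1.09, camera adjusted p = 0.00443); Adam8 rose by 3.22 (SE 0.35) and Timp1 by 2.85 (SE 0.51). The list of matrix proteases and inhibitors had a camera adjusted p = 0.36 with an estimated correlation. Of 24 collagen and extracellular matrix genes, Thbs1 rose by 4.05 (SE 0.63) and 6 fell, and adjusted over the list alone 1 rose and 10 fell (median −1.15, camera adjusted p = 0.00298). The list of collagen and extracellular matrix genes had a camera adjusted p = 0.674 with an estimated correlation. Col1a1, the main chain of type I collagen (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042, plus strand), fell from 15440 ± 5927 to 2196 ± 1748 CPM (SD, n = 5 per group; log2 fold change −2.81, SE 0.74, edgeR adjusted p = 0.0184), and the elastin gene Eln changed by −1.60 (SE 0.41). Col3a1 had a log2 fold change of −1.76 (SE 0.71, edgeR adjusted p = 0.0901). Camera also called the lists of endothelial genes (median 0.86, adjusted p = 0.00232; adjusted p = 0.662 with an estimated correlation, and 0.0755 without diabetic wound replicates 4 and 5) and immediate early genes (0.76, adjusted p = 0.0171; adjusted p = 0.656 with an estimated correlation) higher.

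Of 18 adipocyte genes, 9 fell over all genes tested and 10 fell adjusted over the list alone (median log2 fold change −1.55, camera adjusted p = 3.18e-07), among them Acvr1c (−3.75, SE 0.45) and Thrsp (−3.99, SE 0.64). The list of adipocyte genes had a camera adjusted p = 0.36 with an estimated correlation. Of 16 sebaceous gland genes, 6 fell and 11 fell adjusted over the list alone (median −1.50, camera adjusted p = 2.22e-06), among them Scd3, Dgat2 and Fads2. The list of sebaceous gland genes had a camera adjusted p = 0.36 with an estimated correlation. Of 9 melanocyte genes, 6 fell, including the melanin synthesis genes Dct (−4.91, SE 1.05) and Tyrp1 (−4.74, SE 1.14), while Gpnmb, which macrophages also express, rose; adjusted over the list alone 8 fell and 1 rose (median −3.69, camera adjusted p = 0.00202). The list of melanocyte genes had a camera adjusted p = 0.582 with an estimated correlation. The pigment transporter gene Slc45a2 had 1 count in diabetic wound, a ratio of normal skin to diabetic wound of 202 (95% counting interval 36.3 to 7995). Normal skin replicate 5 held 9.21 CPM of Slc45a2 where the group mean was 2.52 CPM. Without it the log2 fold changes of Slc45a2, Dct and Tyrp1 were −5.43 (−6.99 with all libraries), −3.75 and −3.24. Without diabetic wound replicate 3 Slc45a2 was fitted at −8.42 and Tyrp1 was at −5.33. That replicate held the single count of Slc45a2, so the counts do not set the size of the value of −8.42. Of 20 T and NK cell markers, 9 fell and 13 fell adjusted over the list alone (median −1.51, camera adjusted p = 6.24e-06); Cd3e fell from 3.92 ± 2.04 to 0.362 ± 0.117 CPM and Cd4 from 13.1 ± 10.6 to 1.73 ± 1.78 CPM (SD, n = 5 per group; edgeR adjusted p = 0.00363 and 0.0133). The list of T and NK cell markers had a camera adjusted p = 0.36 with an estimated correlation. The log2 fold change of Cd4 was −2.92, or −2.30 without normal skin replicate 4 and −3.65 without diabetic wound replicate 3, and Thrsp was at −4.58 without diabetic wound replicate 4.

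Of 28 hair follicle and hair keratin genes, 13 fell and 25 fell adjusted over the list alone (camera adjusted p = 3.31e-06). The list of hair follicle and hair keratin genes had a camera adjusted p = 0.649 with an estimated correlation. The list's median log2 fold change was −8.15 as fitted and −7.16 with its 11 members at 0 counts in diabetic wound set to their bounds. Krt25, an inner root sheath keratin gene, had 0 counts in the diabetic wounds and was at least 8654-fold lower there, and Krt35, a hair cortex keratin gene, at least 1601-fold lower, with a floor of 3 counts over the group. The comparison group was itself mixed: Krt71 was at 439, 285 and 1812 CPM in normal skin replicates 3, 4 and 5, and at 0 and 4.93 CPM in replicates 1 and 2. Both bounds rest mostly on normal skin replicate 5, with 1154 CPM of Krt25 and 228 CPM of Krt35 where the group means were 324 and 59.9 CPM. The call of Krt25 was lost without diabetic wound replicate 5, and that of Krt35 without replicate 2 or 5. Reads of hair keratin genes can be shared between relatives in the family.

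By edgeR, 1827 genes were higher and 1445 lower in diabetic wound than in normal skin at a Benjamini-Hochberg adjusted p under 0.05. Of these called genes, 798 higher and 533 lower ones had a mean of at least 10 CPM and groups that did not overlap. The 0.794% that chance gives for genes not chosen by a test is no baseline for called genes. The count of 3272 genes called in all became 2060 and 2029 in fits without diabetic wound replicates 2 and 5. It was 3824 and 3510 without replicates 3 and 4, and 1994 without replicates 4 and 5 together. A fit of these 2 groups alone called 1430. A total of 44 of the 50 named genes that passed did so in all 10 fits that left out 1 library. Camera called 5 more lists. Myofibroblast genes (median −0.86, adjusted p = 0.00642; adjusted p = 0.592 with an estimated correlation), dendritic cell and MHC class II genes (−0.78, adjusted p = 0.00323; adjusted p = 0.608 with an estimated correlation) and cornified epidermal genes (−1.21, adjusted p = 2.23e-05; adjusted p = 0.649 with an estimated correlation, and 0.0517 without diabetic wound replicates 4 and 5) were lower. Skeletal muscle genes (median −1.20, camera adjusted p = 0.00883, or adjusted p = 0.701 with an estimated correlation) were lower as well, but were not called without diabetic wound replicate 3 (camera adjusted p = 0.194). Wound-edge keratinocyte genes (median 1.18, camera adjusted p = 0.0119, or adjusted p = 0.68 with an estimated correlation) were higher, but not without normal skin replicates 1 and 3 or diabetic wound replicate 3 (adjusted p = 0.0535, 0.0553 and 0.116).

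Both wound groups were set against the same libraries of healthy normal skin, which asks whether the same genes differed from it in both. Since uninjured diabetic skin was not analysed, wounding and diabetes cannot be told apart in the diabetic comparison. In both comparisons 101 genes were called higher and 38 lower, where lists drawn independently would share 14.2 and 5.06. None were called in opposite directions. Across the 17122 genes the log2 fold changes had a Pearson correlation of 0.508 and a Spearman correlation of 0.482. However, 20 simulated pairs of unchanged wound groups against the shared controls gave a mean Pearson correlation of 0.501 and at most 0 shared calls. They called only 0.05 and 0 genes higher on average, so their count of shared calls carries no weight. The covariance was 0.473, against 0.111 in the simulations. With normal skin split so that each wound group had its own 2 or 3 control libraries, 10 splits gave a mean Pearson correlation of 0.343 and a mean covariance of 0.349, with 3 genes shared higher and 1.6 shared lower on average. These fits called far fewer genes, on average 59.8 and 56.1 higher and 50.3 and 50.7 lower in healthy and diabetic wound. Lists drawn independently would share 0.607 and 0.392 of them.

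Camera called lists of collagen, myofibroblast and T cell genes lower in diabetic than in healthy wound (each adjusted p = 0.36 with an estimated correlation), and single genes such as Ppbp, Lyz1 and the clock repressor gene Cry2 rose. This comparison asks how wound RNA differed between diabetic and healthy mice. Strain, time after wounding and the way diabetes was induced are not given. If any of these, or the handling of the samples, differed between the groups, it cannot be told apart from diabetes in this comparison. Ppbp, which encodes a platelet and myeloid chemokine (ENSMUSG00000029372; chromosome 5, 90768518 to 90770063, plus strand), rose from 7.64 ± 3.88 CPM in healthy wound to 156 ± 98.6 CPM in diabetic wound (SD, n = 5 per group; log2 fold change 4.35, SE 0.57, edgeR adjusted p = 0.00461). Lyz1, a lysozyme gene, rose by 3.46 (SE 0.60), Chil3, a chitinase-like gene of macrophages, by 3.88 (SE 0.99) and the metallothionein gene Mt2 by 3.25 (SE 0.74), with edgeR adjusted p-values of 0.0108, 0.0303 and 0.0218; each has a close relative with which reads can be shared. The nonagouti gene a (chromosome 2, 154791402 to 155051012, plus strand), which encodes a signal for yellow pigment, rose from 0.963 ± 0.469 to 14.6 ± 10 CPM (log2 fold change 3.91, SE 0.77, edgeR adjusted p = 0.016), but its model overlaps Raly and Eif2s2, so the source of its reads is uncertain. Among the largest falls were Prss35, a protease-like gene (−7.37, SE 1.71), and Prr9, a proline-rich gene (−6.86, SE 1.69), with edgeR adjusted p-values of 0.0237 and 0.0283. None of Chil3, Mt2, Prss35 and Prr9 was called without healthy wound replicate 5, where Prss35 was at −5.65. Prr9 was at −4.65 without healthy wound replicate 2 and −7.87 without diabetic wound replicate 3, and Lyz1 at 2.85 without diabetic wound replicate 2.

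Of 24 collagen and extracellular matrix genes, 13 fell over all genes tested and 20 fell adjusted over the list alone (median log2 fold change −1.88, camera adjusted p = 5.63e-09). The list of collagen and extracellular matrix genes had a camera adjusted p = 0.36 with an estimated correlation. Col12a1 (ENSMUSG00000032332; chromosome 9, 79598991 to 79718831, minus strand) fell from 1000 ± 684 to 96.2 ± 29.2 CPM (SD, n = 5 per group; log2 fold change −3.38, SE 0.68, edgeR adjusted p = 0.016). Col1a1 changed by −3.08 (SE 0.74), Col3a1 by −2.48 (SE 0.73), Col6a1 by −2.13 (SE 0.41) and Postn, the matricellular protein periostin, by −3.10 (SE 0.65), with edgeR adjusted p-values of 0.0265, 0.0454, 0.0149 and 0.0175. Of 15 myofibroblast and contractile genes, 8 fell and 9 fell adjusted over the list alone (median −1.19, camera adjusted p = 9.31e-05). The list of myofibroblast and contractile genes had a camera adjusted p = 0.36 with an estimated correlation. They included Acta2, smooth muscle actin, from 291 ± 81.3 to 97.2 ± 29.6 CPM (log2 fold change −1.58, SE 0.28, edgeR adjusted p = 0.0121), Itga11, a collagen receptor (−2.85, SE 0.70), and Lrrc15, a marker of activated fibroblasts (chromosome 16, 30269302 to 30283256, minus strand), from 321 ± 242 to 5.71 ± 6.24 CPM (−5.81, SE 1.13, edgeR adjusted p = 0.0152). The collagen share of counts was 5.22 ± 2.63% in healthy wound and 0.784 ± 0.610% in diabetic wound. None of Col1a1, Col3a1, Postn and Itga11 was called without healthy wound replicate 5, where Postn was at −2.43. Without diabetic wound replicate 3, Itga11 was at −3.49 and Lrrc15 at −6.57.

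Of 20 T and NK cell markers, 6 fell and 13 fell adjusted over the list alone (median log2 fold change −1.71, camera adjusted p = 3.18e-07). The list of T and NK cell markers had a camera adjusted p = 0.36 with an estimated correlation. Cd4 fell from 17.0 ± 7.40 to 1.73 ± 1.78 CPM (SD, n = 5 per group; log2 fold change −3.29, SE 0.72, edgeR adjusted p = 0.0193), Ncr1, a natural killer cell receptor gene, changed by −3.47 (SE 0.95), and Cd8b1 had 2 counts in diabetic wound, a ratio of healthy to diabetic wound of 23.0 (95% counting interval 6.37 to 189.9). All 22 interferon-stimulated genes had negative fold changes, and 2 fell by either adjustment, among them Ifi44 (−2.79, SE 0.50) (median −1.003, camera adjusted p = 2.22e-06). The list of interferon-stimulated genes had a camera adjusted p = 0.581 with an estimated correlation. Of 25 cell cycle genes none passed by either adjustment in edgeR, against 4936 genes of the whole table with an unadjusted p under 0.05, and 2 had positive fold changes (median −0.53, camera adjusted p = 0.00298). The list of cell cycle genes had a camera adjusted p = 0.701 with an estimated correlation, and 0.143 without diabetic wound replicates 4 and 5. Mki67, a proliferation marker, was at 99.1 ± 66.3 CPM in diabetic wound and 205 ± 43.3 CPM in healthy wound (edgeR adjusted p = 0.176). Camera also called dendritic cell and MHC class II genes lower (median −0.78, adjusted p = 0.00443; adjusted p = 0.63 with an estimated correlation). Cd4 was not called without diabetic wound replicate 2 and was at −4.02 without replicate 3. Ncr1 was not called without healthy wound replicate 5 and was at −4.33 without diabetic wound replicate 4.

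Several metabolic and stress genes were higher in diabetic wound. Of 22 oxidative stress response genes, 5 rose, and adjusted over the list alone 9 rose and 1 fell (median log2 fold change 0.60, camera adjusted p = 0.00195). The list of oxidative stress response genes had a camera adjusted p = 0.36 with an estimated correlation. The superoxide dismutase genes Sod2 and Sod1 rose by 1.87 (SE 0.41) and 1.10 (SE 0.23), and Nqo1, a quinone reductase gene, by 1.44 (SE 0.35), with edgeR adjusted p-values of 0.0193, 0.0173 and 0.0268; Sod1 overlaps Scaf4 on the other strand. Of 26 nuclear oxidative phosphorylation genes, all had positive fold changes, 6 rose and 8 rose adjusted over the list alone (median 0.32, camera adjusted p = 2.17e-06), among them Ndufs3 (0.69, SE 0.14), Ndufb8 (0.79, SE 0.17) and Ndufv1 (0.51, SE 0.12), subunits of respiratory complex I. The list of nuclear oxidative phosphorylation genes had a camera adjusted p = 0.36 with an estimated correlation. These are short genes (median length 2276 bp, against 3868 bp for all genes tested). Of 10000 lists matched on gene length and expression, a test added after the list was called, 15.67% had a median as high. The count-weighted median gene length was 4066 ± 214 bp in diabetic wound and 4487 ± 174 bp in healthy wound, and the pseudogene share of counts 0.829 ± 0.129% and 0.647 ± 0.0611%. Of 17 circadian clock genes, 6 rose and 1 fell, and adjusted over the list alone 12 rose and 3 fell (median 1.04, camera adjusted p = 0.00135). The list of circadian clock genes had a camera adjusted p = 0.582 with an estimated correlation. Cry2 (ENSMUSG00000068742; chromosome 2, 92403646 to 92434043, minus strand) rose from 21.6 ± 3.40 to 173 ± 109 CPM (SD, n = 5 per group; log2 fold change 3.00, SE 0.49, edgeR adjusted p = 0.0106), with 21.5 CPM in diabetic wound replicate 3 and 98.3 to 268 CPM in the others. Cry1 and Nfil3 rose by 1.53 (SE 0.35) and 1.36 (SE 0.27). In the same samples camera called the list of 19 skeletal muscle genes higher in diabetic wound. Of its members 15 had positive fold changes and none passed by either adjustment in edgeR (median 0.75, camera adjusted p = 0.0224; adjusted p = 0.725 with an estimated correlation). The camera call of the muscle list was lost without healthy wound replicates 4 and 5 or diabetic wound replicates 1 and 4 (camera adjusted p = 0.145, 0.138, 0.0578 and 0.115), and without diabetic wound replicates 4 and 5 together (0.283). None of Sod2, Sod1, Nqo1, Ndufs3, Ndufb8, Ndufv1 and Cry1 was called without healthy wound replicate 5.

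The immune lists that were high in both wounds did not pass between them. Of 17 neutrophil markers, Ngp (log2 fold change 6.85, SE 1.51, edgeR adjusted p = 0.0197) and Mmp8 (2.14, SE 0.51, edgeR adjusted p = 0.026) rose by either adjustment, while S100a8 had a log2 fold change of −0.29 (SE 0.61, edgeR adjusted p = 0.786). The neutrophil list was not called between the wounds (median 0.71, camera adjusted p = 0.0632). The Ngp value rested on diabetic wound replicate 5 (2.88 without it), and without it or healthy wound replicates 1 and 5 the gene was not called. Of 22 inflammatory genes, Cxcl1 rose (4.17, SE 1.21, edgeR adjusted p = 0.0448; 1.98 and adjusted p = 0.232 without diabetic wound replicate 5) and none passed adjusted over the list alone (median 0.24, camera adjusted p = 0.533). Il6, Tnf, Il1b, Nos2 and Il10 had log2 fold changes of 3.05 (SE 1.11), 0.69 (SE 0.97), −0.38 (SE 1.10), −1.12 (SE 0.87) and 0.60 (SE 0.45), with edgeR adjusted p-values of 0.0902, 0.666, 0.845, 0.405 and 0.393. Of 17 monocyte and macrophage markers, Itgam rose (1.50, SE 0.34) and Cx3cr1 fell (−2.57, SE 0.76) by either adjustment (median −0.10, camera adjusted p = 0.721); the Cx3cr1 model overlaps Xirp1 and other genes. Arg1 and Mrc1, both used as markers of alternatively activated macrophages, had log2 fold changes of 0.87 (SE 0.52, edgeR adjusted p = 0.279) and 0.02 (SE 0.51, edgeR adjusted p = 0.982). None of Mmp8, Cxcl1, Itgam and Cx3cr1 was called without healthy wound replicate 5, and Cx3cr1 was at −3.51 without diabetic wound replicate 3.

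Hair genes were lower in diabetic wound: 13 of 28 fell and 26 fell adjusted over the list alone (camera adjusted p = 1.66e-06; adjusted p = 0.649 with an estimated correlation), with a median log2 fold change of −9.64 as fitted and −9.39 with the 11 members at 0 counts set to their bounds. Krt25, Krt73 and Krt35 were at least 9440-fold, 2190-fold and 1259-fold lower, with a floor of 3 counts over the group. Krt71 (ENSMUSG00000051879; chromosome 15, 101733949 to 101743109, minus strand) and Krt28 each had 1 count in diabetic wound. The ratio of healthy to diabetic wound was 54670 for Krt71 (95% counting interval 9813 to 2159000) and 3659 for Krt28 (656.8 to 144500), intervals that cover counting error only. Krt71 was at 2717, 533.7 and 158.6 CPM in healthy wound replicates 2, 4 and 5 and at 0.445 and 0 CPM in replicates 1 and 3. Krt25, Krt73 and Krt35 were at 1314, 278 and 164 CPM in healthy wound replicate 2, where the group means were 353, 82.0 and 47.1 CPM. Of the 10 fits that left out 1 library, 3, 2 and 2 called these genes, 7 called Krt71 and 6 called Krt28. Camera called 4 more lists lower: sebaceous gland genes (median −0.84, adjusted p = 0.00563; adjusted p = 0.582 with an estimated correlation), melanocyte genes (−2.09, adjusted p = 0.0303, or 0.674 with an estimated correlation), adipocyte genes (−0.30, adjusted p = 0.0329, or 0.701 with an estimated correlation) and cornified epidermal genes (−0.73, adjusted p = 0.0282, or 0.725 with an estimated correlation). The camera call of the melanocyte list was lost without healthy wound replicate 4 or diabetic wound replicates 4 and 5 (camera adjusted p = 0.104, 0.0803 and 0.079), and without diabetic wound replicates 4 and 5 together (0.263). The camera call of the adipocyte list was lost without healthy wound replicates 2 and 3 or diabetic wound replicates 1, 2 and 3 (camera adjusted p = 0.0744, 0.0723, 0.109, 0.115 and 0.0962). The camera call of the cornified list was lost without healthy wound replicates 3 and 4 or diabetic wound replicates 4 and 5 (camera adjusted p = 0.0723, 0.147, 0.472 and 0.144), and it turned upward without diabetic wound replicates 4 and 5 together (0.283).

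**Figure D2:**
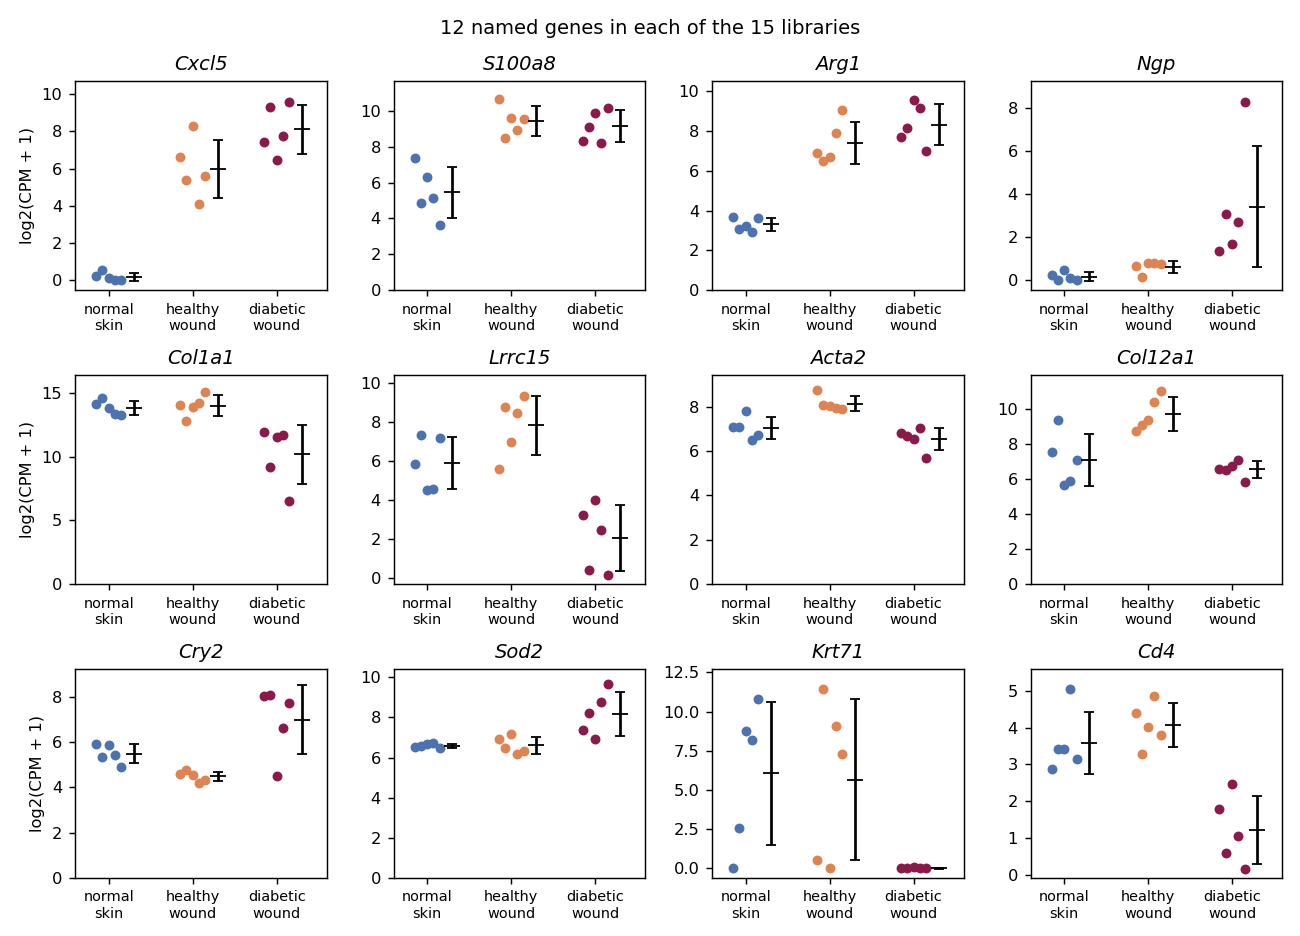
Expression of 12 named genes as log2(CPM + 1) in each library (points) of the 3 groups, with the mean and SD of the 5 libraries of each group (bars). Cxcl5, S100a8 and Arg1 are higher in both wound groups than in normal skin, Lrrc15, Acta2 and Col12a1 are lower in diabetic than in healthy wound, and Krt71 varies between libraries of normal skin and healthy wound.

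The remaining lists were not called between the wounds. Camera adjusted p-values were 0.0527 for immediate early and heat shock genes, 0.0748 for alternatively activated macrophage genes, 0.0949 for wound-edge keratinocyte genes, 0.105 for B and plasma cell markers and 0.141 for glycation, insulin and glucose response genes. For growth factors, hypoxia genes, homing ligands, endothelial genes and matrix proteases the camera adjusted p-values were 0.179, 0.296, 0.309, 0.454 and 0.468. Camera also did not call basal keratinocyte genes, mast cell markers, Schwann cell genes or red blood cell genes (camera adjusted p = 0.614, 0.824, 0.861 and 0.992). The red blood cell list had a median of −0.02 and a mean of −0.71 while camera ranked it upwards. Pecam1, Vegfa and Tgfb1 had log2 fold changes of −0.28 (SE 0.32), 0.42 (SE 0.39) and −0.47 (SE 0.24), with edgeR adjusted p-values of 0.584, 0.496 and 0.2. The keratin genes Krt6a and Krt10 had log2 fold changes of −0.50 (SE 0.83) and −0.93 (SE 0.79), with edgeR adjusted p-values of 0.723 and 0.453.

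By edgeR, 878 genes were higher and 689 lower in diabetic wound than in healthy wound at a Benjamini-Hochberg adjusted p under 0.05, and 4936 had an unadjusted p under 0.05. Of these called genes, 474 higher and 313 lower ones had a mean of at least 10 CPM and groups that did not overlap. The 0.794% that chance gives for genes not chosen by a test is no baseline for called genes. The count of 1567 genes called in all became 400, 744, 807, 477 and 230 in fits without healthy wound replicates 1 to 5 in turn. It was 854, 252, 2925, 1934 and 517 without diabetic wound replicates 1 to 5 in turn, and 658 without diabetic wound replicates 4 and 5 together. A fit of these 2 groups alone called 801. Of the 39 named genes that passed, 11 did so in all 10 fits that left out 1 library: Ppbp, Lyz1, a, Cry2, Nfil3, Col12a1, Col6a1, Lrrc15, Acta2, Ifi44 and Cd8b1.

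**Figure D3:**
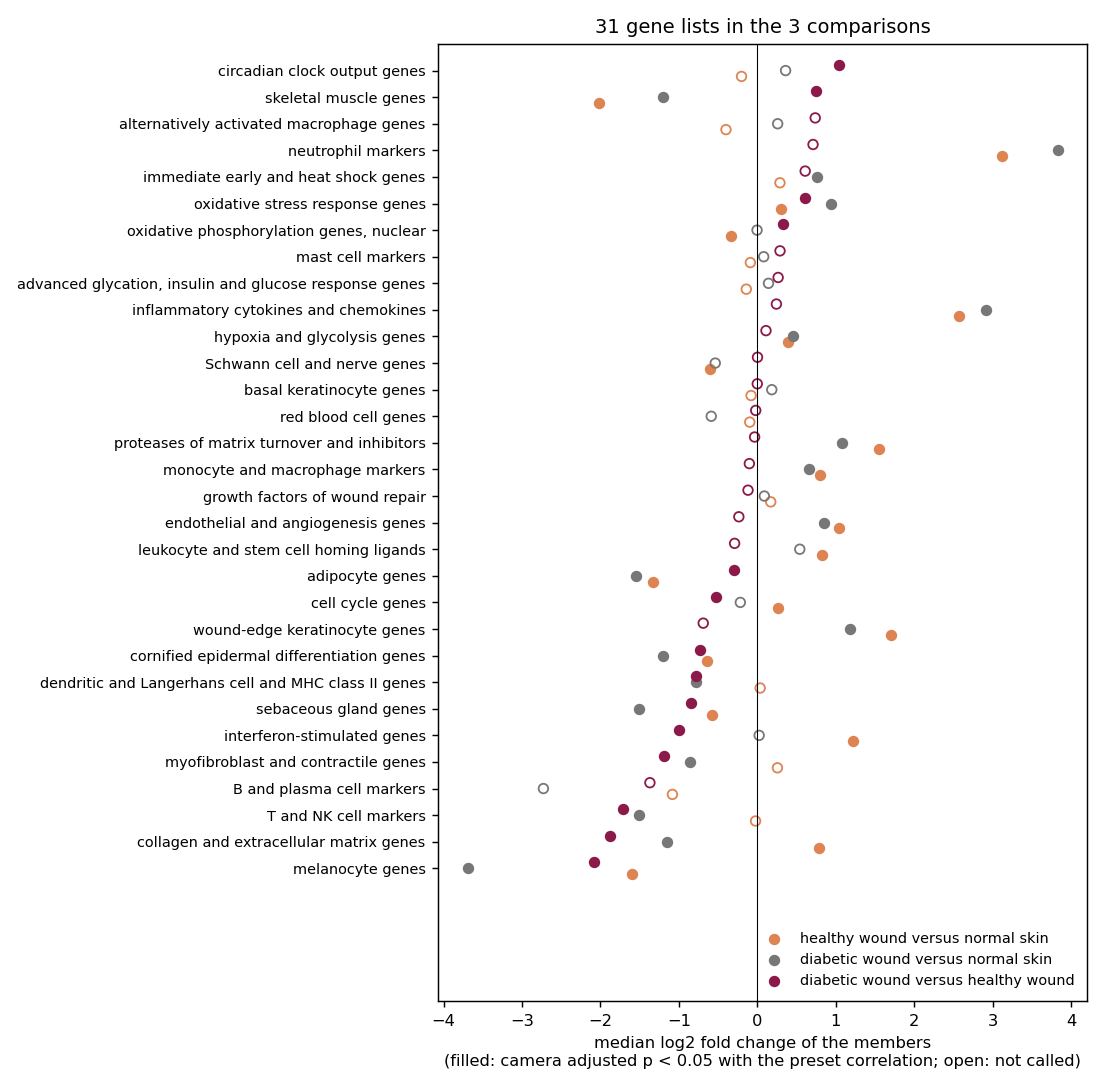
Median log2 fold change of the members of 31 gene lists (the hair list, whose medians lie far below the others, is left out) in the 3 comparisons; filled points were called by camera at an adjusted p under 0.05 with the preset correlation and open points were not. The collagen list lies at 0.79 in healthy wound and −1.15 in diabetic wound against normal skin, and at −1.88 between the wounds; no list was called with an estimated correlation.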

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

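For the collagen pattern weighed here, all 3 tests were written down before their results were seen. Other values in this part are libraries that stood far from the other 4 of their group, by Dixon's test at a critical ratio of 0.71, which chance exceeds in about 1 of 20 groups. The test singled out 3 of 21 groups of library measures (14.3%), 6 of 96 groups of list means (6.2%) and 19 of 354 groups of named genes (5.4%).

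Of the library measures, normal skin replicate 2 had 0.1188% of counts in models without a symbol (others 0.0836 to 0.0933%) and a count-weighted median gene length of 5194 bp (others 4196 to 4390 bp), and diabetic wound replicate 2 had 0.1459% hemoglobin counts (others 0.0541 to 0.0713%). Of the list means in log2 CPM, healthy wound replicate 2 was at 2.942 for neutrophil markers (others 4.819 to 5.328) and at 6.505 for oxidative stress genes (others 6.359 to 6.396). Healthy wound replicate 5 was at 4.552 for adipocyte genes (others 5.796 to 6.154). Diabetic wound replicate 3 was at 6.516 for skeletal muscle genes (others 8.59 to 9.074) and diabetic wound replicate 4 at 7.162 for oxidative stress genes (others 6.603 to 6.758). Normal skin replicate 1 was at 6.572 for immediate early genes (others 5.179 to 5.447).

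Of the named genes in log2 CPM, normal skin replicate 1 stood apart for Prokr2 (0.757) and Cxcl3 (3.201), replicate 2 for Gpd1 (7.664) and Lyz1 (2.337), replicate 4 for Defb3 (−0.565) and Cd4 (5), and replicate 5 for Hmcn2 (5.895), Angpt2 (0.545) and Gbp3 (3.018). Healthy wound replicate 1 stood apart for Acta2 (8.765), replicate 2 for Ngp (−2.121), and replicate 3 for Mb (6.941) and Cry1 (4.604). Diabetic wound replicate 1 stood apart for Krt28 (−2.449), replicate 3 for Lep (0.383), Krt71 (−2.465) and Slc45a2 (−2.465), replicate 4 for Adh6a (−1.732) and replicate 5 for Ngp (8.281). For Krt28, Krt71 and Slc45a2 the library that stood apart held the single count of the group.

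The list of collagen and extracellular matrix genes had a median log2 fold change of −1.879 between the wounds (camera adjusted p = 0.36 with an estimated correlation). Against normal skin the medians were 0.786 in healthy wound and −1.149 in diabetic wound (camera adjusted p = 0.649 and 0.674 with an estimated correlation), and no gene was called in opposite directions. A single library setting the fall was excluded, since the highest median over the 10 fits that left out 1 library was −1.653. Loss of long transcripts was excluded, since 0% of 10000 lists matched on length and expression had a median as low. A smaller share of fibroblasts, as 22 fibroblast markers measure it, was excluded as the whole cause of the difference between the wounds. Collagen genes relative to these markers still differed by −1.145 on the log2 scale (exact p = 0.00794, the smallest possible), although the markers also differed by −0.769 (exact p = 0.0397). However, 2 of the markers, Gsn and Abca8a, were called lower in healthy wound than in normal skin (−1.65 and −1.78). The list may therefore miss fibroblasts that make collagen in a wound, and a smaller share of those was not tested. In collagen genes relative to the markers, the diabetic wounds (1.939 to 2.741) lay within normal skin (1.937 to 3.157) and below the healthy wounds (3.291 to 3.814). For the fall against normal skin, where the fibroblast markers had a median of −0.883, a smaller share of fibroblasts therefore stays open.

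Whether group labels given at random would call as many genes was asked with fits of 2 groups alone. Among 100 of the 126 splits of 10 libraries, only the real one, 1 of 100, called as many genes in each comparison. The real splits called 537 genes in healthy wound against normal skin (highest other 2), 1430 in diabetic wound against normal skin (highest other 8) and 801 between the wounds (highest other 4). Labels given at random are therefore an unlikely source of these counts. A mixed split carries the group difference into the spread within its groups, which lowers its count. The counts of the fit over 3 groups were not tested in this way. The splits also cannot show what set the groups apart, or whether libraries shared an animal.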

How the results depend on the processing

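RLE, upper-quartile and library-size scaling and limma-voom kept every count of called genes within 1.5 times, and no called gene among those named changed direction under any setting. A fold minimum lowers a count by construction. The counts of healthy wound against normal skin rose when diabetic libraries were left out, which that comparison does not use. The single fit over the 3 groups therefore bears on how many genes each comparison called. Whether its filter, its scaling or its estimate of spread did so was not tested, nor was the cause of the other changes below. Leaving out libraries lowered some counts and raised others. Counts are higher and lower genes. Healthy wound against normal skin (133 and 60) had 70 and 21 with no low-count filter, 88 and 36 with the stricter filter, 624 and 448 by DESeq2, 984 and 869 by limma-voom with quality weights, 331 and 206 with 2 groups alone, 66 and 25 with the replicate block, and 369 and 236 without diabetic wound replicates 4 and 5. Diabetic wound against normal skin (1827 and 1445) had 1189 and 949 with no filter, 815 and 615 with 2 groups alone, 1169 and 825 without replicates 4 and 5, 2297 lower by DESeq2, 916 lower with the block, and 966 higher with the fold minimum. Diabetic against healthy wound (878 and 689) had 281 and 293 with no filter, 1628 and 1442 by DESeq2, 2063 and 1986 with quality weights, 438 and 363 with 2 groups alone, 81 and 92 with the block, 382 and 276 without replicates 4 and 5, and 350 higher with the fold minimum. Leaving out each library gave 3 to 208 and 0 to 61, 1188 to 2056 and 792 to 1768, and 120 to 1481 and 100 to 1444, in the same order. Lists called higher and lower were 11 to 12 and 5 to 8, 8 to 9 and 10 to 13, and 4 to 6 and 9 to 11.

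With an estimated correlation 0 lists were called higher and 0 lower in each comparison. By fry 8 lists were higher and 2 lower in healthy wound against normal skin, 5 higher and 4 lower in diabetic wound against normal skin, and 2 higher and 5 lower between the wounds. Genes shared by both wounds (101 and 38) were 65 and 25 with the stricter filter and 3 and 1.6 on average with normal skin split. The split fits called only 59.8 and 56.1 genes higher and 50.3 and 50.7 lower on average. Without diabetic wound replicates 4 and 5, chosen after the data were seen, basal keratinocyte genes turned higher against normal skin (camera adjusted p = 0.0322) and healthy wound (0.0189), and cornified genes turned upward between the wounds without a call (0.283). The libraries were not taken as paired, since not every correlation of libraries with the same number was over 0.1. These ran from −0.054 to 0.238 (4 of 5 over 0.1, 2 of 5 best with their own number), −0.203 to 0.014 (0 and 0) and −0.21 to 0.1 (0 and 1), so a partial pairing of healthy wound with normal skin stays open.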

Other observations

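The genes in this paragraph and the next were chosen after their values were seen. Their calls in fits that left out 1 library are not given here. Without healthy wound replicate 5 only 230 genes were called between the wounds, against 1567 with all libraries. Between the wounds, diabetic wounds had more transcript of Txnip, the thioredoxin-interacting protein gene that responds to glucose, at 824 ± 432 CPM against 331 ± 78.6 CPM (SD, n = 5 per group; log2 fold change 1.32, SE 0.36, edgeR adjusted p = 0.0365). Its relative Arrdc4 rose by 0.82 (SE 0.24, edgeR adjusted p = 0.0481). The insulin-like growth factor binding protein gene Igfbp3 rose from 153 ± 24.6 to 488 ± 326 CPM and Igfbp5 fell from 445 ± 130 to 87.3 ± 60.8 CPM (edgeR adjusted p = 0.0208 and 0.0193). Of 20 genes of glycation, insulin and glucose response, 4 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone, without a call for the list (camera adjusted p = 0.141).

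Of the growth factor genes, Tgfb3 fell from 47.9 ± 13.9 to 12.3 ± 5.36 CPM and Pdgfb changed by −1.14 (SE 0.32) on the log2 scale (edgeR adjusted p = 0.021 and 0.0393). Fosl1, a subunit of the AP-1 transcription factor, rose from 11.1 ± 4.77 to 42.2 ± 21.2 CPM (edgeR adjusted p = 0.029).

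For the pattern of retroviral gene models, the test on the count of called models without single libraries was written before its result was seen and the other 3 after. Of 51 models without a symbol but with a retroviral description, 19 rose and 0 fell between the wounds in edgeR (median log2 fold change 2.14), against 878 higher and 689 lower of all 17122 genes. Over all genes 4936 had an unadjusted p under 0.05. The share of counts in the 51 models was 0.267 ± 0.165% in diabetic wound and 0.0612 ± 0.00915% in healthy wound. The 205 other models had a median of 0.114, which argues against more reads from unannotated sequence of every kind. A permutation over gene models gave p = 1e-05 for the difference, the smallest possible. Gene models are not independent replicates, so that p does not measure the spread between libraries. The count of models called higher was 9 without healthy wound replicate 5, 10 without replicate 1 and 11 without replicate 4, and it was 11 without diabetic wound replicate 2 and 26 without replicate 3, so how far single libraries set this count cannot be told apart from a rise in all. One library as the holder of the larger share was excluded. The diabetic libraries held 0.087 to 0.502% and the healthy libraries 0.0469 to 0.0709%, and the mean share was at least 3.41 times as large without any 1 library (exact p = 0.00794, the smallest possible). Reads of 1 copy counted at many models and a rise of many copies cannot be told apart, since the called models had a median pairwise correlation of 0.639 over the diabetic libraries. No biological explanation was tested.

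For the higher Cry2, Per1, Mt1 and Mt2 in diabetic than in healthy wound, the glucocorticoid test was written before its result was seen and the tests of muscle and of time of day after, and the exact p asked of the time test was added once a first version had excluded it. A glucocorticoid response may contribute. The 19 glucocorticoid targets, in no other list, had a median log2 fold change of 1.406, with 7 called higher, among them Klf9, Errfi1 and Sgk1. Their mean log2 CPM was higher by 0.913 (exact p = 0.0238 for this mean). Against normal skin, however, the median of the targets was 0.398 in diabetic wound and −0.328 in healthy wound. Part of the difference between the wounds was thus a lower level in healthy wound. The list of targets had a camera p of 4.55e-06 between the wounds, and 0.0942 with an estimated correlation. For this test of 5 against 5 libraries the exact p is the one relied on. Its mean log2 CPM went with that of the muscle list among the wounds. Diabetic wound replicate 3 was lowest of its group in both (5.693 and 6.516) and replicate 4 highest (6.991 and 9.074). Normal skin, with the highest mean of muscle genes, had 5.112 to 6.483 for the targets. How far muscle content adds to this list was not tested. More muscle was excluded as the whole cause, since the lowest log2 fold change of the 4 genes against normal skin was 1.922 while the muscle list was at −1.20. A part of muscle in the difference between the wounds was not tested. There the muscle list had a median of 0.75, and diabetic wound replicate 3 was lowest of its group in muscle genes and in Cry2. Another time of day at harvest cannot be told apart from other causes, since genes on the Arntl side had a median of 0.624 and those on the Nr1d1 side 0.914, with exact p = 0.0317 and 0.349 for their mean log2 CPM.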
